A study of Drosophila melanogaster with 9 samples.

How the data were processed

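The estimated counts per gene and library were used as deposited, and per the labels they came from a workflow whose tools the submitters' processing notes list as fastp 0.18.0, HISAT2 2.1.0, StringTie 1.3.1 and RSEM, without the version of RSEM or the step each tool served. The log2 fold changes in the authors' 2 deposited comparison tables were ratios of the group means of FPKM, as recomputed from the deposited mean columns. The p-value and FDR columns of these tables were deposited by the authors, with a differential test that is not given in the sources used here. The FPKM columns themselves were not used here. The genome build of the deposited processing is not given in the sources used here, and gene coordinates were taken from the BDGP6.54 annotation, release 115, with 1-based positions.

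The count table held 14168 entries, of which 13963 had a FlyBase identifier (13918 present in the reference annotation) and 205 were loci assembled from the reads. In all, 2283 entries had no counts in any library, and 0 count columns belonged to other series. Between 8.20% and 9.11% of the values in a library were not whole numbers, and these were rounded before fitting. Libraries had between 9729 and 10358 genes with counts, and mitochondrial genes took 1.90% to 2.41% of counts. A floor of 3 counts corresponded to 0.150 to 0.211 CPM. Floors and counting intervals (95% confidence) cover counting error alone, not variation between animals. Where a group had 0 counts the fold change was given as a lower bound, from 3 counts over the group.

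Groups followed the genotype in the labels, with 3 libraries each. The comparisons, tests, gene lists and alternatives were fixed before the data were examined, apart from those named here as later. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM normalisation, filterByExpr and the robust quasi-likelihood test over all 9 libraries, with Benjamini-Hochberg adjustment over 8487 genes, and a gene was called at an adjusted p under 0.05. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 105 tests of 35 lists in 3 comparisons. The common biological coefficient of variation was 3.61%, and Pearson correlations of replicate pairs ran from 0.994 to 0.995. DESeq2 1.42.0 served as an alternative. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

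Genes were named by a rule: the targeted and driver genes, 15 list members chosen beforehand and given whatever their p, the 8 called genes of each direction with the largest fold changes, a mean of at least 5 CPM in the higher group and no overlap between libraries, and up to 4 members with the smallest adjusted p from each list that passed or had at least 3 called members. CG17716 in the double knockdown was named outside the rule. The dosage compensation gene roX1 was not analysed here. The single value of white (w) is given for the double knockdown against control only. Of 236 named genes with a position, 84 overlapped exons of another gene and 6 shared at least 20% of their exon bases with a gene in the table.

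The pipeline was tried on simulated counts in which 8347 genes were tested and 50 were changed at each simulated fold in the NAT10 knockdown. This is a far smaller share than the 62.1% of genes called in the real NAT10 knockdown. Recovery and false calls were therefore not tried under so broad a change. In the NAT10 knockdown against control 34 of 50 genes were recovered at 1.25-fold, 44 at 1.5-fold, 48 at 2-fold and 50 at 4-fold, with 14 false calls among 190. In the double knockdown against control the recovered shares were 62.5%, 88.5%, 91.7% and 100%, with 7 false calls among 93. In the double knockdown against the NAT10 knockdown they were 73.1%, 91.7%, 96.2% and 100%, with 7 false calls among 97. Of 100 genes simulated back at the control level 89 were called in the NAT10 knockdown and all 89 were counted as changed back, while 1 gene simulated as retained was counted as changed back.

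The alternatives were the DESeq2 Wald test, other size factors, total counts only, no filter (11885 genes), a filter of 5 CPM in 3 libraries (7191 genes), only the 2 genotypes compared in the fit, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, and a 2-fold threshold. For lists they were an estimated correlation, fry in place of camera, and the block. Limiting the genes to those with at least 1 CPM in control or the NAT10 knockdown, and leaving out the assembled loci, were added after the results were seen. The Malpighian tubule, midgut and second fat body lists were also written after the results were seen. The second fat body list was picked from a longer set of candidates, limited to genes that had passed the filter, so these lists test nothing and their p-values are not given. Enrichment of annotated processes in the genes changed at least 2-fold used Fisher's exact test over 835 terms against a background of 6621 annotated genes.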

Results

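Polyadenylated RNA was sequenced from wing imaginal discs, the larval epithelial sacs that form the adult wing and part of the thorax, of Drosophila melanogaster in the third larval instar. The 9 libraries fell into 3 genotypes with 3 biological replicates each, and each RNA extraction pooled 100 discs. Control discs carried the engrailed-GAL4 driver alone. In the NAT10 knockdown the driver expressed RNA interference against NAT10, an RNA cytidine acetyltransferase that modifies ribosomal RNA. In the double knockdown it also expressed RNA interference against Xrp1, a bZIP transcription factor that mediates the response to ribosomal protein loss. The driver is active in the posterior compartment, so each library of whole discs mixes targeted and untargeted cells. The design asks how far the transcript changes of the NAT10 knockdown depend on Xrp1. The control libraries held 18161577, 14183856 and 17183487 estimated counts. The NAT10 knockdown libraries held 17519054, 17036250 and 17952301 and the double knockdown libraries 19664722, 17981108 and 19949448. Levels are normalised CPM (counts scaled by library size and TMM factor), as mean ± SD over the 3 libraries of a genotype, and log2 fold changes are given ± SE. The first principal component took 56.4% of the variance and set the NAT10 knockdown apart from both other genotypes, and the second, with 32.6%, set the control apart from the double knockdown.

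The targeted genes were lower in the libraries whose labels name them. The fly NAT10 gene is listed as l(1)G0020 (FBgn0027330, X, 8716713 to 8720277, minus strand, in the BDGP6.54 annotation). Its level was 101 (100.6, 103 and 100.7 in the single libraries) in control, 62.2 (61.4, 63.2 and 62.1) in the NAT10 knockdown and 74.7 (75.1, 77.1 and 71.8) in the double knockdown. It fell by 0.70 ± 0.042 on the log2 scale in the NAT10 knockdown (adjusted p = 6.2e-14) and by 0.44 ± 0.041 in the double knockdown (adjusted p = 2.38e-09). Xrp1 (FBgn0261113, 3R, 18914968 to 18926989, plus strand) stood at 521 (510.6, 526 and 525) in control, rose to 941 (944, 954 and 924) in the NAT10 knockdown and was 409 (425, 406 and 397) in the double knockdown. Against control its log2 fold change was 0.85 ± 0.028 in the NAT10 knockdown (adjusted p = 1.29e-19) and -0.35 ± 0.028 in the double knockdown (adjusted p = 1.81e-10). The driver locus engrailed (en, FBgn0000577, 2R, 11524006 to 11528210, minus strand) was at 101 (103.7, 98.5 and 101) in control, 61.7 (62.0, 60.8 and 62.2) in the NAT10 knockdown and 71.8 (71.3, 71.0 and 73.1) in the double knockdown, and both decreases passed (adjusted p = 3.12e-14 and 1.96e-10). Its neighbour inv, also a posterior compartment gene, fell by 0.43 ± 0.051 in the NAT10 knockdown (adjusted p = 3.83e-08) and did not pass in the double knockdown (-0.04 ± 0.049, adjusted p = 0.56).

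**Figure D1:**
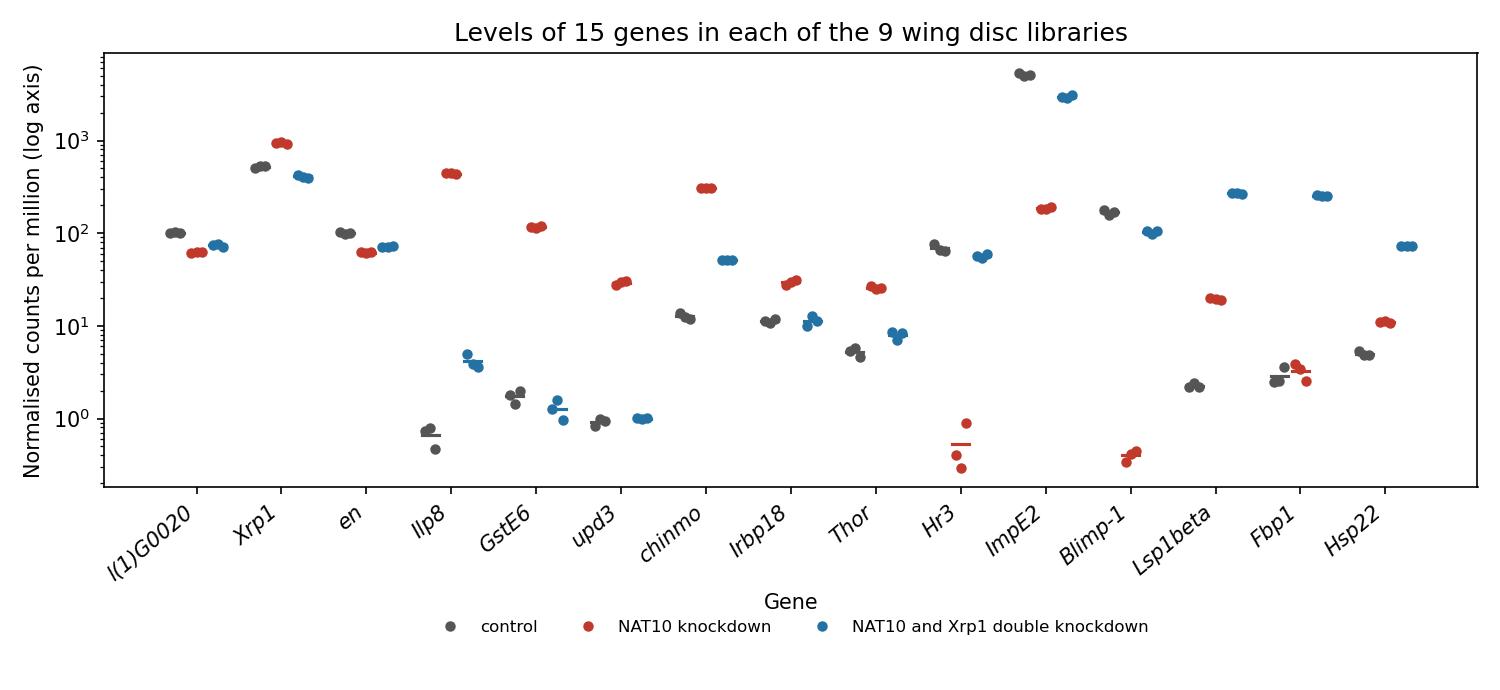
Normalised CPM on a log axis for 15 genes in each of the 9 libraries, with a point per library and a bar at the mean of the 3 libraries of a genotype. Ilp8 reaches 440.5 in the NAT10 knockdown against 0.658 in control and 4.13 in the double knockdown, while Fbp1 reaches 252 in the double knockdown alone.

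Knockdown of NAT10 was compared with the driver control to see which transcripts change when the enzyme is depleted. The relaxin-like peptide Ilp8, which damaged discs secrete to delay pupariation, rose from 0.658 ± 0.166 to 440.5 ± 5.10 (669-fold; log2 9.39 ± 0.080, adjusted p = 6.67e-32). The glutathione transferase GstE6 rose 66.1-fold, the cytokine upd3 31.6-fold and the BTB transcription factor chinmo 24.1-fold (adjusted p = 6.65e-27, 2.31e-21 and 1.05e-30). Genes induced by the steroid ecdysone were among those with the largest decreases. The transcriptional repressor Blimp-1 went from 168 ± 10.1 to 0.400 ± 0.052 and the nuclear receptor Hr4 from 164 ± 10.9 to 1.23 ± 0.419 (adjusted p = 2.62e-29 and 8.22e-16). Among 8487 genes tested, 2757 were higher and 2511 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 571 and 371 of these differed at least 2-fold. The libraries of the genotypes did not overlap for 65.6% of genes, where chance gives 10%.

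Of 12 tested members of a list of Xrp1 partners and genes known from ribosomal protein mutants, 10 were higher and 1 lower over all genes tested (10 and 2 adjusted over the list alone), and the list stood above other genes (camera, adjusted p = 1.54e-08). They included Irbp18, the C/EBP-family partner of Xrp1, which went from 11.3 ± 0.626 to 29.6 ± 1.85 (log2 1.39 ± 0.089), and Ku80, a DNA end-joining factor, at log2 1.29 ± 0.057. Among 13 JAK-STAT ligands and targets 9 were higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 3.3e-09), with upd1 up 5.75-fold and the feedback inhibitor Socs36E up 2.20-fold. The JNK target list also passed (adjusted p = 1.86e-08), although its 26 members split into 13 higher and 10 lower (the same counts adjusted over the list alone). The JNK phosphatase puc was not among those that passed (log2 0.10 ± 0.048, adjusted p = 0.0719; 0.0461 without control replicate 1 and 0.0483 with total counts only), and the matrix metalloprotease Mmp1 rose by only 0.15 ± 0.037. In the DNA damage response list 16 of 20 members were higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 2.15e-05), among them mre11 (2.40-fold), rad50 (2.08-fold) and the Ku70 gene Irbp (2.84-fold). These 4 list calls held when the correlation between genes was estimated, but the JNK call was lost in the fit with a replicate block. Over the 3 comparisons 17 of the 37 list calls held with an estimated correlation.

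Glutathione transferase and oxidative stress genes were higher in 20 and lower in 9 of 41 cases (21 and 9 adjusted over the list alone; camera adjusted p = 0.00234, but adjusted p = 0.0607 with an estimated correlation). GstD9 rose 9.15-fold and catalase (Cat) fell from 459 ± 12.8 to 250 ± 5.17. Cytosolic ribosomal protein genes were higher in 64 and lower in 1 of 84 cases (66 and 1 adjusted over the list alone), by a median log2 of 0.23 (camera adjusted p = 0.000365; adjusted p = 0.591 with an estimated correlation). RpL27A rose 1.43-fold. Thor, which encodes the translation repressor 4E-BP, rose 4.89-fold (adjusted p = 1.6e-16), while crc, the fly ATF4 gene, rose 1.22-fold. The count of crc is uncertain, because it shares 73.5% of its exon bases with CG46314. The list of ATF4 targets as a whole did not pass (13 higher and 5 lower of 21, camera adjusted p = 0.862). In that list the serine synthesis enzyme gene CG6287 fell by 2.40 ± 0.047 and Gadd45 rose by 1.00 ± 0.040 on the log2 scale. The pro-apoptotic gene rpr rose 1.87-fold (adjusted p = 6.25e-08), hid fell by 0.16 ± 0.038 (adjusted p = 0.000921), and the caspase inhibitor Diap1 fell by 0.46 ± 0.027. Lactate dehydrogenase (Ldh) rose 1.85-fold. Dif, an NF-kappaB-type factor of the Toll pathway, rose 14.1-fold. In all, 5 of 7 immunity genes were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.116 with an estimated correlation), a call also lost with a replicate block.

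All but 1 of 32 proteasome subunit genes fell (31 also adjusted over the list alone; median log2 -0.31, camera adjusted p = 1.28e-05, held with an estimated correlation), with Rpn2 going from 487 ± 10.1 to 338 ± 10.3. Of 18 endoplasmic reticulum stress genes 14 were lower and 2 higher (14 and 2 adjusted over the list alone; camera adjusted p = 5.05e-06, held with an estimated correlation). The chaperones Pdi, Hsc70-3 and Gp93 and the transcription factor Xbp1 fell by 1.05 ± 0.024, 1.03 ± 0.024, 0.82 ± 0.025 and 0.89 ± 0.030 on the log2 scale. Wing patterning genes were lower in 35 and higher in 4 of 45 cases (36 and 4 adjusted over the list alone; camera adjusted p = 3.27e-07, but adjusted p = 0.184 with an estimated correlation). The intervein factor gene bs, the vein-spacing gene kn and the distal selector Dll fell 2.82-fold, 5.05-fold and 2.36-fold. Of the compartment signalling genes, hh fell by 0.14 ± 0.045 (adjusted p = 0.00784) and its receptor gene ptc did not pass (187 ± 3.03 in control and 186 ± 4.59 in the knockdown, adjusted p = 0.889).

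Of 22 members of the ecdysone response list 12 were lower and 3 higher (the same counts adjusted over the list alone). The camera adjusted p of the list was 1.57e-26 at the preset correlation and 0.0104 with an estimated one. ImpE2 went from 5181 ± 187 to 186 ± 6.71, ImpE1 from 768 ± 34.4 to 36.9 ± 1.89, the nuclear receptor gene Hr3 from 68.8 ± 6.99 to 0.528 ± 0.317 and Eip78C from 88.4 ± 4.17 to 1.54 ± 0.161. Hr3 shares 58.0% of its exon bases with the listed gene CG46321, so its count is uncertain. The nuclear receptor gene ftz-f1, whose transcripts normally rise after an ecdysone pulse has passed, was 6.51-fold higher (16.6 ± 0.505 against 108 ± 0.850). Cuticle protein genes went both ways, 16 higher and 9 lower of 31 (the same adjusted over the list alone; camera adjusted p = 0.936), with Cpr49Ah up 10.1-fold and Cpr49Ac down from 429 ± 11.5 to 27.8 ± 2.00.

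Transcripts of other cell types also differed between these genotypes. Fat body genes were higher in 9 and lower in 2 of 12 cases (the same adjusted over the list alone; camera adjusted p = 0.00115, but adjusted p = 0.187 with an estimated correlation), as for the storage protein Lsp1beta, at 2.25 ± 0.140 in control and 19.3 ± 0.517 in the knockdown. Disc epithelium genes were lower in 15 of 16 cases, such as shg, which encodes E-cadherin (log2 -0.44 ± 0.026; camera adjusted p = 0.00277, adjusted p = 0.0605 with an estimated correlation; 15 adjusted over the list alone). In the muscle list 12 of 16 were lower and 3 higher (the same adjusted over the list alone, camera adjusted p = 0.0978). The list passed in the fit with a replicate block. It also passed with fry, which does not compare a list with other genes and called 87 of the 105 list tests. The salivary gland list had only 2 tested members, of which CrebA, also a secretory pathway factor, fell by 1.52 ± 0.040 (1 lower adjusted over the list alone; camera adjusted p = 0.0167, adjusted p = 0.184 with an estimated correlation; also lost with a replicate block). Beyond the lists, the genes with the largest increases included AOX1, which encodes an aldehyde oxidase (0.669 ± 0.048 to 90.0 ± 1.40), the cytochrome P450 gene Cyp6a20 (a ratio of 113.8, counting interval 38.6 to 554.5, from 3 control counts) and CG14695 (a ratio of 499.5, counting interval 137.9 to 4130, from 2 control counts).

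The double knockdown was compared with the driver control to see what remained changed when Xrp1 was depleted as well. Fat body and heat shock lists had the smallest camera p. The storage protein genes Lsp1beta and Lsp2 rose to 269 ± 4.68 and 260 ± 4.86, from 2.25 ± 0.140 and 2.78 ± 0.378 in control. The storage protein gene Lsp1gamma rose 92.4-fold and the fat body receptor gene Fbp1 86.4-fold. Hsp68 rose 9.98-fold, from 33.6 ± 2.21 to 337 ± 4.52. Hsp22 rose 14.5-fold, from 5.02 ± 0.293 to 72.9 ± 0.087, but its count is uncertain, because 100% of its exon bases lie in exons of CG4456. Of the 8487 genes 1335 were higher and 1318 lower by edgeR's test with Benjamini-Hochberg adjustment, of which 331 and 58 differed at least 2-fold. With libraries scaled by total counts alone the split was 1613 higher and 1044 lower, so the share of higher genes was 60.7% in place of 50.3%. The libraries did not overlap for 42.4% of genes, where chance gives 10%.

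Of 22 tested heat shock and chaperone genes 14 were higher and 5 lower than in control (15 and 5 adjusted over the list alone). The camera adjusted p of this list was 7.16e-86 at the preset correlation and 0.000295 with an estimated one. The 6 listed Hsp70 copies are nearly identical and share reads, so the sum of the copies was used: 178 ± 2.04 in control, 429.6 ± 4.99 in the NAT10 knockdown and 2232 ± 34.1 in the double knockdown. Of 12 fat body genes 9 were higher and none lower, with 3 not passing (the same adjusted over the list alone, median log2 4.48). The camera adjusted p of the fat body list was 2.5e-169 at the preset correlation and 0.000295 with an estimated one. Several genes with the largest fold changes had 0 counts in all control libraries. The alkaline phosphatase genes Alp7, Alp4 and Alp8 stood at 43.5 ± 3.93, 11.8 ± 1.15 and 11.4 ± 1.03, at least 726-fold, 197-fold and 189-fold above control for a floor of 3 counts over the group, and CG17752 was at least 303-fold higher. The mucin gene Muc11A had a ratio of 1475.5 (counting interval 504.6 to 7157) over 3 control counts. In a list of Malpighian tubule genes written after these were seen and holding Alp4, 9 of 13 were higher and 1 lower (11 and 1 adjusted over the list alone), which is no test because of how it was chosen. Of 2 tested midgut genes neither passed.

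Proteasome genes were lower in 20 of 32 cases (22 adjusted over the list alone; median log2 -0.14; camera adjusted p = 0.000216, adjusted p = 0.0605 with an estimated correlation). Endoplasmic reticulum stress genes were lower in 9 of 18 (10 adjusted over the list alone; camera adjusted p = 0.00924, adjusted p = 0.138 with an estimated correlation), with Hsc70-3 at log2 -0.33 ± 0.024. Of 13 JAK-STAT genes 4 were higher (4 adjusted over the list alone; camera adjusted p = 0.0133, adjusted p = 0.0967 with an estimated correlation), among them the stress peptide gene TotA, at 0.129 ± 0.079 in control and 2.39 ± 0.369 in the double knockdown. Muscle genes were lower in 11 and higher in 2 of 16 cases (11 and 3 adjusted over the list alone; camera adjusted p = 0.0185, adjusted p = 0.254 with an estimated correlation), including Mhc, the muscle myosin heavy chain gene, from 7.10 ± 0.883 to 2.06 ± 0.300. The crystal cell enzyme gene PPO2 fell from 6.55 ± 0.941 to 1.83 ± 0.252, although the hemocyte list as a whole did not pass (3 higher and 4 lower of 15, the same adjusted over the list alone; camera adjusted p = 0.374). Of 5 genes used as transgene markers 4 were higher and 1 lower: yellow (y) stood at 8.29 ± 1.29 against 0.195 ± 0.109, vermilion (v) was at least 20.1-fold above a control with 0 counts, and white (w) rose 1.15-fold (the same counts adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.179 with an estimated correlation). In the NAT10 knockdown against control 0 of these 5 were higher and 3 lower (camera adjusted p = 0.763). In the double knockdown against the NAT10 knockdown 4 were higher and 0 lower (camera adjusted p = 0.0896). Some genes of the NAT10 knockdown stayed above control, with Ilp8 at 4.13 ± 0.708 (log2 2.65 ± 0.195, adjusted p = 3.14e-11), chinmo at 51.3 ± 0.569 (2.02 ± 0.055), ftz-f1 at 39.6 ± 1.34 (1.26 ± 0.057) and Thor at 8.06 ± 0.851 (0.62 ± 0.119, adjusted p = 0.000197). Others did not pass against control: Irbp18 (11.2 ± 1.35, adjusted p = 0.938), upd3 (0.998 ± 0.008, adjusted p = 0.788), rpr (log2 0.19 ± 0.115, adjusted p = 0.239), puc (adjusted p = 0.12) and GstE6 (1.27 ± 0.320, adjusted p = 0.0978; 0.0429, and lower than control, without double knockdown replicate 2). Mmp1, crc, hid, hh and Ldh were below control by 0.28 ± 0.037, 0.14 ± 0.026, 0.25 ± 0.038, 0.20 ± 0.044 and 0.44 ± 0.111 on the log2 scale, and ptc was above it by 0.12 ± 0.030.

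The ecdysone response list had 6 higher and 12 lower members of 22 against control (6 and 13 adjusted over the list alone). Its camera test did not pass (adjusted p = 0.985), but it passed with the opposite sign in the fit with a replicate block. Its median was below 0 (-0.22) while its mean was above it (0.23); the list also holds Fbp1. ImpE1 and ImpE2 fell by 0.73 ± 0.031 and 0.80 ± 0.033, to 462 ± 6.69 and 2966 ± 131. The 12 members that were lower in the NAT10 knockdown had a median level of 6.74% of control there and 74.6% of control in the double knockdown. In the wing patterning list 7 genes were higher and 8 lower of 45 (8 and 8 adjusted over the list alone; camera adjusted p = 0.643), with bs and kn down by 0.30 ± 0.040 and 0.40 ± 0.064.

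The double knockdown was then compared with the NAT10 knockdown, to see what differs when Xrp1 is targeted as well. These genotypes also differ in the number of constructs and in the level of NAT10 transcript, so differences are not those of Xrp1 depletion alone. Ilp8 was 106-fold lower than in the NAT10 knockdown, GstE6 91.9-fold, upd3 29.1-fold and chinmo 5.95-fold (adjusted p = 1.12e-31, 2.14e-27, 1.34e-21 and 2.58e-27). Blimp-1 was 252-fold higher, ImpE2 15.9-fold and ImpE1 12.5-fold (adjusted p = 7.38e-28, 1.03e-25 and 6.8e-30). Xrp1 itself was 2.30-fold lower (adjusted p = 9.6e-23), while l(1)G0020 was 1.20-fold higher (log2 0.26 ± 0.042, adjusted p = 7.11e-06). NAT10 transcript in whole discs was thus less reduced with both constructs than with the single one. Depletion within the targeted cells was not measured, and transcript of the driver locus en was also lowest in the NAT10 knockdown. Of 8487 genes 2413 were higher and 2400 lower, 489 and 408 of them at least 2-fold, by edgeR's test with Benjamini-Hochberg adjustment. The libraries did not overlap for 63.0% of genes, where chance gives 10%.

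Most lists that had moved in the NAT10 knockdown moved the other way here. Of the Xrp1 partner and ribosomal protein mutant genes 9 were lower and 1 higher of 12 (the same adjusted over the list alone; camera adjusted p = 9.75e-11). Xrp1 itself, the target of the second construct, is a member and 1 of the 9. Of the others, Irbp18 fell by 1.40 ± 0.087 and Ku80 by 1.29 ± 0.055. JAK-STAT genes were lower in 8 and higher in 3 of 13 cases, JNK targets lower in 14 and higher in 10 of 26, and DNA damage genes lower in 12 and higher in 1 of 20 (8 and 3, 14 and 10, and 13 and 1 adjusted over the lists alone; camera adjusted p = 1.5e-07, 4e-10 and 1.25e-05). Glutathione and oxidative stress genes were lower in 19 and higher in 8 of 41 cases (19 and 9 adjusted over the list alone; camera adjusted p = 0.000851). All of these held with an estimated correlation. Cytosolic ribosomal protein genes were lower in 57 and higher in 1 of 84 cases (58 and 1 adjusted over the list alone; camera adjusted p = 0.000533, adjusted p = 0.591 with an estimated correlation), as for RpL27A (log2 -0.37 ± 0.025). Thor fell by 1.67 ± 0.093, rpr by 0.72 ± 0.104, Ldh by 1.33 ± 0.103, Mmp1 by 0.43 ± 0.037, crc by 0.42 ± 0.026 and puc by 0.20 ± 0.047. Dif fell by 2.78 ± 0.067, and 5 of 7 immunity genes were lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.023, adjusted p = 0.137 with an estimated correlation). The decrease of hid was at the edge of the threshold (-0.09 ± 0.038, adjusted p = 0.0483): it did not pass without control replicate 3 (0.0615), without NAT10 knockdown replicate 1, 2 or 3 (0.0714, 0.208 and 0.277) or without double knockdown replicate 1 or 2 (0.0876 and 0.291). It also did not pass by the DESeq2 Wald test (0.174), with DESeq2 size factors (0.0872), with total counts only (0.0817) or with a filter of 5 CPM in 3 libraries (0.0875). The values for hh did not pass (adjusted p = 0.311), and ptc was higher by 0.13 ± 0.029.

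In the other direction, 15 of 22 ecdysone response genes were higher and 3 lower (the same adjusted over the list alone). The camera adjusted p of the ecdysone list was 1.5e-35 at the preset correlation and 0.0066 with an estimated one. Wing patterning genes were higher in 37 and lower in 1 of 45 cases (38 and 1 adjusted over the list alone; camera adjusted p = 1.79e-07, adjusted p = 0.179 with an estimated correlation), with kn, bs and Dll up 3.82-fold, 2.29-fold and 2.19-fold. Proteasome genes were higher in 28 of 32 cases (29 adjusted over the list alone; camera adjusted p = 0.0171, adjusted p = 0.184 with an estimated correlation) and endoplasmic reticulum stress genes in 13 of 18, with 2 lower (14 and 2 adjusted over the list alone; camera adjusted p = 0.00115, adjusted p = 0.0734 with an estimated correlation). Disc epithelium genes were higher in 15 of 16 cases (15 adjusted over the list alone; camera adjusted p = 0.00447, adjusted p = 0.063 with an estimated correlation). Heat shock and chaperone genes were higher in 18 and lower in none of 22 cases (the same adjusted over the list alone, camera adjusted p = 2.92e-35). Hsp27 went from 639.6 ± 15.6 to 1980.3 ± 28.4, but it was at least 2-fold lower in the NAT10 knockdown than in control. Part of its rise was therefore a return toward control. In the NAT10 knockdown against control this list had 10 higher and 10 lower members and did not pass (camera adjusted p = 0.918). Fat body genes were higher in 9 and lower in 2 of 12 (the same adjusted over the list alone; camera adjusted p = 1.99e-41). The heat shock and fat body calls against the NAT10 knockdown held with an estimated correlation (adjusted p = 0.000295 and 0.00379). The 2 salivary gland genes were both higher (2 adjusted over the list alone; camera adjusted p = 0.0437, adjusted p = 0.258 with an estimated correlation). The mucin gene Muc11A was at least 1564-fold higher than in the NAT10 knockdown, where it had 0 counts, and Fst, a cold and desiccation response gene, had a ratio of 1478 (counting interval 408.8 to 12209).

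**Figure D2:**
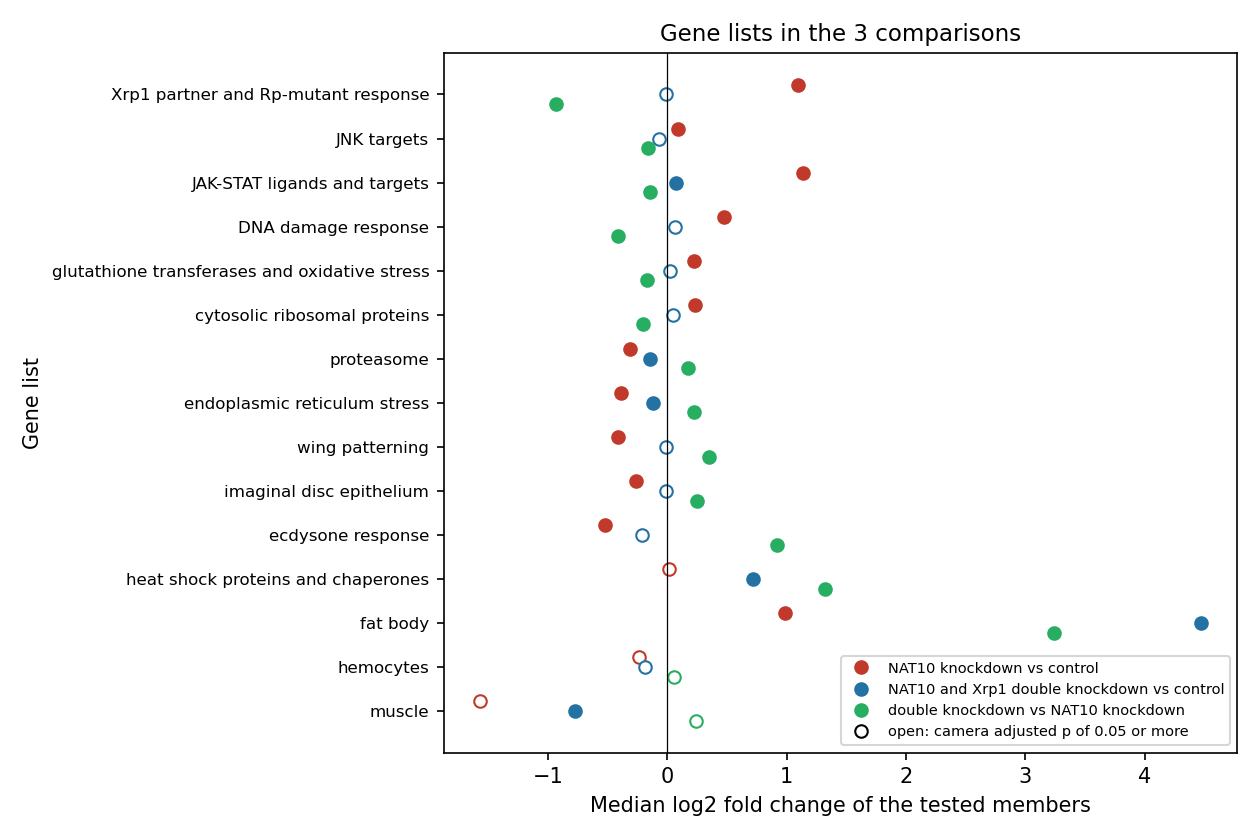
Median log2 fold change of the tested members of 15 gene lists in the 3 comparisons, with filled points where the camera test passed at the preset correlation and open points where it did not. The fat body list has the highest median against control in the double knockdown (4.48), and the Xrp1 partner list goes from 1.09 in the NAT10 knockdown to -0.01 in the double knockdown, both against control.

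The share of the NAT10 knockdown changes that were undone in the double knockdown was counted from these fits. Of the 5268 genes called in the NAT10 knockdown, 3912 (74.3%) were changed back in the double knockdown, that is, also called with the opposite sign against the NAT10 knockdown. These were 2000 of the 2757 higher genes and 1912 of the 2511 lower ones, and 785 of the 942 genes that had differed at least 2-fold. Among the last, 458 of 571 higher genes, such as Ilp8, GstE6 and upd3, and 327 of 371 lower genes, such as Blimp-1 and ImpE1, were changed back. A gene counted as retained was called with the same sign in the double knockdown against control. This held for 1879 genes (35.7%), of which 1176, such as chinmo and Thor, were changed back in part, and 653 genes met neither rule. CG17716, chosen after its values were seen, was retained, at 13.6 ± 0.868 in the NAT10 knockdown and 12.5 ± 0.917 in the double knockdown against 0.042 ± 0.037 in control. In 20 simulations in which the double knockdown had the means of the NAT10 knockdown, a mean of 0.5 genes was counted as changed back and 4825.8 as retained. Independent lists of these lengths would share 1493.6 genes for the first count and 823.6 for the second. The double knockdown carried a further construct and held more l(1)G0020 transcript in whole discs (74.7 against 62.2). No group had a control construct in place of the one against Xrp1. The genes changed back therefore combine the effect of Xrp1 depletion with any effect of the further construct or of a weaker NAT10 depletion. Any difference in larval stage between the genotypes would be included as well, because stage within the third instar was not measured.

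Both comparisons with control share its libraries, so their fold changes correlate without any effect. Across genes, which are not independent replicates, the correlation between the NAT10 knockdown and the double knockdown changes was 0.321, against 0.519 in simulations with no effect, and the covariance was 0.293 against 0.010. The difference of the covariances, 0.283, estimates the shared effect. Part of the excess of retained genes over independent lists may come from the shared controls, which are too few to split. Of the 2653 genes called in the double knockdown against control, 1879 were called with the same sign in the NAT10 knockdown, 221 with the opposite sign and 553 were not called there, which is no test of a difference. In the direct comparisons 191 genes were at least 2-fold higher than in both other genotypes, while 23 were at least 2-fold lower.

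**Figure D3:**
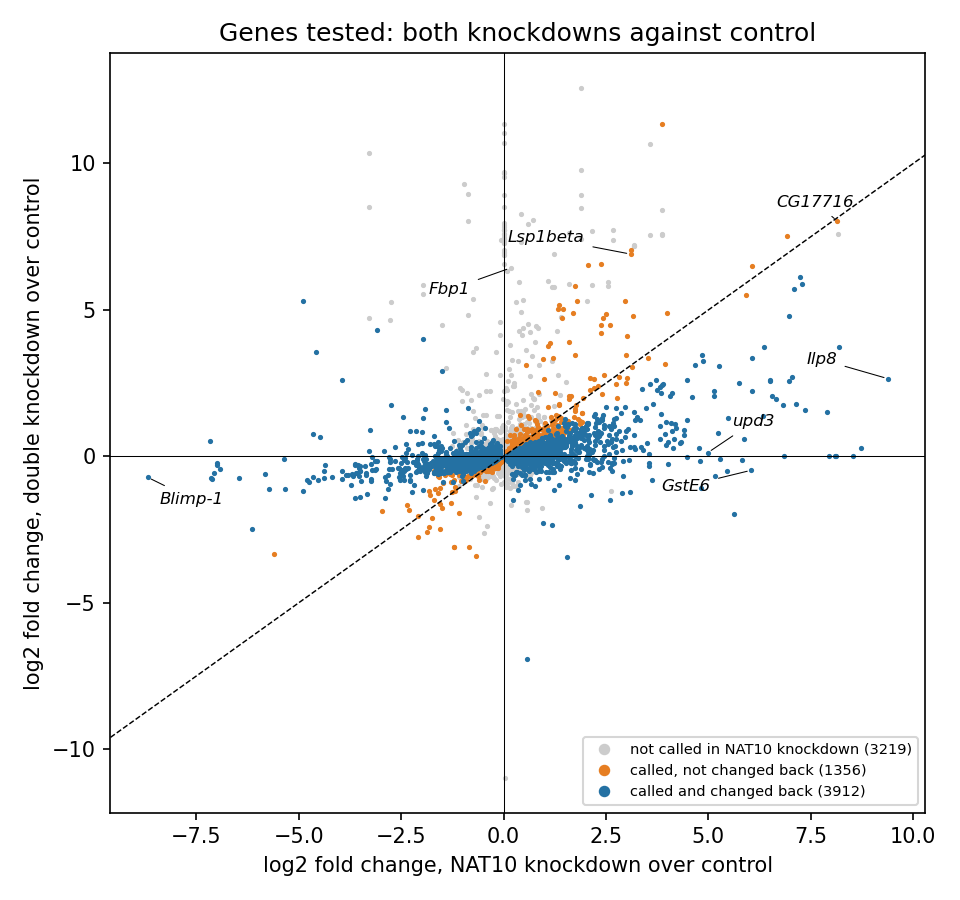
Log2 fold change against control of the 8487 genes tested, NAT10 knockdown on the x axis and double knockdown on the y axis, with 1 point per gene coloured by whether it was called in the NAT10 knockdown and changed back; fitted values of genes with 0 counts in a group depend on the model's prior count. The 3912 genes called and changed back lie mostly between the dashed line of equal change and the line at 0, and Lsp1beta and Fbp1 lie above both.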

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

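The limits to genes with at least 1 CPM in control or the NAT10 knockdown and to genes outside assembled loci were chosen after the results were seen. A 2-fold threshold left 942, 389 and 897 genes in the 3 comparisons (NAT10 knockdown against control, double knockdown against control, double against NAT10 knockdown) and 607 genes changed back. No other alternative moved any of these gene counts by more than 1.5-fold, while the count of list calls moved further, as given below. With 1 library left out the gene counts ran from 4910 to 5340, 2284 to 2661 and 4460 to 5025, and genes changed back from 3612 to 3919. The DESeq2 Wald test called 4782, 2206 and 4355 genes with 3458 changed back. The limit to 1 CPM gave 5178, 2414 and 4578 genes, and the fit without assembled loci 5174, 2636 and 4709. The labels give the genotypes the same replicate numbers, and with the replicate block 5282, 2675 and 4839 genes were called and 3935 changed back. Deviations of libraries with the same number correlated from -0.028 to 0.077 across genes, so pairing was not visible in the values. Of 37 list calls 17 remained with an estimated correlation, fry called 87 lists, and the replicate block called 39. In the NAT10 knockdown against control the block ended the calls of the JNK (adjusted p = 0.282), immunity (0.0926) and salivary gland lists (0.257). It added those of ribosome biogenesis (0.00829; 31 higher and 7 lower of 55), muscle (0.0128) and adult muscle progenitors (0.0244; 2 higher and 9 lower of 11), and of cuticle proteins in the double knockdown against control (0.019). With the block the ecdysone list of the double knockdown against control passed with the opposite sign (adjusted p = 0.0349, against 0.985 without it), and the cause was not tested. No named gene passed with opposite signs in any 2 fits that tested it (23 values had no adjusted p in an alternative), and with 1 library left out 38 calls were lost, 6 gained and 3961 stayed the same. The biological coefficient of variation was low (3.61%), so small fold changes passed, but the replicates were not equally alike. Chi-square per degree of freedom was 5.85 and 5.28 for control replicate 1 against the others and 2.14 between those, and 5.75 and 6.02 for double knockdown replicate 3 against the others and 2.21 between those. The labels do not say whether the replicates came from separate crosses or days, and variation between such batches may not be covered.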

Other observations

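The tests of handling, pulse timing, driver domain, Hsp70 reads, transgene sequence and tissue share below were chosen only after the result was seen, while the splits of libraries and the depth test were set before the data were examined. Loci assembled from the reads and annotated as retroelements or transposons held 4214.9 CPM in control, 30486.9 in the NAT10 knockdown and 4858.4 in the double knockdown. Most of the sum came from 3 loci, 2 annotated as copia (14001 and 8994 CPM in the NAT10 knockdown) and 1 as blastopia (4579), and the median log2 change of the class against control was 1.247. Of 47 such loci 34 were higher and 3 lower in the NAT10 knockdown against control, and 34 were lower and 4 higher in the double knockdown against the NAT10 knockdown. In the double knockdown against control 17 were higher and 11 lower (median log2 0.154), so not all were back at the control level. Some loci annotated as opus stayed above control there, by log2 2.36 to 2.47. Several loci share an annotation, such as copia or opus, so these are counts of loci and not of independent elements. Among genes at least 2-fold higher in the NAT10 knockdown, cuticle development (22 of 67 annotated genes, adjusted p = 8.56e-10) and glutathione metabolism (12 of 32, adjusted p = 1.25e-05) were enriched by Fisher's exact test, with 2 further terms. Among those at least 2-fold lower there the terms were proteolysis (22 of 193, adjusted p = 0.00448), mesoderm development (10 of 50, adjusted p = 0.00515), cell fate commitment (7 of 23, adjusted p = 0.00515) and male courtship (6 of 23, adjusted p = 0.0406). Among genes at least 2-fold higher in the double knockdown against control, transmembrane transport (43 of 227, adjusted p = 6.68e-20), cuticle development (15 of 67, adjusted p = 5.16e-07), the response to unfolded protein (6 of 13, adjusted p = 0.000252) and the response to heat (10 of 49, adjusted p = 0.000325) were among 11 enriched terms. The 6 unfolded protein genes were Hsp68 and Hsp70 copies that share reads, and the 10 heat genes included the same copies. Fisher's exact test counted these copies as separate genes, so the adjusted p-values of both terms overstate the evidence. Among those at least 2-fold lower the terms were myofibril assembly (4 of 10, adjusted p = 9.95e-05), sarcomere organization (4 of 27, adjusted p = 0.00391) and mesoderm development (4 of 50, adjusted p = 0.0314). The authors' deposited tables held 2881 genes with an FDR under 0.05 in the NAT10 knockdown, of which 97.0% were called here with the same sign. In the double knockdown they held 1940, 1869 higher and 71 lower, of which 70.1% were called here. There Xrp1 had an FDR of 0.547 and l(1)G0020 of 0.209, while both were called here.

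When the 6 libraries of a comparison were split in all 10 ways into groups of 3, only the real split, 1 of 10, called any gene: 5195, 2486 and 4877 genes, with 0 as the highest other count. Only 10 splits are too few for a share under 0.05. For the genes changed back, 1 of 100 groupings of the 9 libraries, the real one, reached 3912, and the highest other count was 3284. Exchanging the labels of the control and the double knockdown leaves this count unchanged by its definition. The groupings drawn therefore do not test a return toward control.

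The ecdysone response genes that were low in the NAT10 knockdown were weighed against 3 explanations. Genes matched on control abundance had a median log2 change of -0.096, which is against lower depth or a few genes taking the reads. All 12 stood at 40% to 100% of control in the double knockdown. However, Eip55E, Hr39, Eip75B and br already stood in that range in the NAT10 knockdown (90.98%, 58.37%, 48.44% and 45.15%), so they show no return by this bound. The others returned, as they would if the NAT10 knockdown discs had been taken before the late larval ecdysone pulse. Stage and genotype coincide, so this cannot be told apart from an effect of Xrp1. Of the 12, 7 were under 10% of control in whole discs of the NAT10 knockdown, lower than a change limited to the cells of the driver domain would give if the other cells made them, but where they are made was not measured.

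The fat body transcripts that were high in the double knockdown were weighed against 2 explanations. The muscle and hemocyte lists had median log2 changes of -0.78 and -0.19 (standard errors of members 0.228 and 0.187). The muscle value is against a lower share of disc epithelium raising the markers of every other cell type. However, the muscle list was lower still in the NAT10 knockdown (-1.57), so its decrease need not reflect tissue share. The disc epithelium list itself had a median of -0.009 in the double knockdown, with 5 of 16 members lower and 0 higher. A second fat body list that shares no gene with the first had a median of 1.356, with 6 of 8 genes higher, but its genes were picked after the pattern was seen and among detected genes. It decides nothing, so RNA from other larval tissue cannot be told apart from transcription in the disc. The 6 abundant fat body transcripts summed to 14.8 CPM in control, 66.9 in the NAT10 knockdown and 1345.9 in the double knockdown, with coefficients of variation from 1.74% to 4.78% among the 3 double knockdown libraries, so unequal carry-over between replicates was not seen.

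The heat shock genes that were high in the double knockdown were weighed against 3 explanations. Summed over the 6 Hsp70 copies the log2 ratio to control was 3.65, which is against reads shared between copies. Without these copies the list still passed (camera p = 3.13e-15 at the preset inter-gene correlation, 0.000889 with an estimated correlation), which is against Hsp70 promoter sequence in a transgene as the only source. Yet only 8 of the 16 remaining members were higher and 5 were lower, with a median log2 change of 0.13 against 0.72 for the full list, so this rise rests on a few members. Of the list, 12 members, 6 of them Hsp70 copies that share reads, were higher in the double knockdown than in both other genotypes, and since handling and genotype coincide this cannot be told apart from handling of the discs.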
